A study of Mus musculus with 2 samples.

How the data were processed

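Lacrimal glands of CD1 mice were collected at embryonic day 16 and postnatal day 4, per the labels. According to the labels' protocol the glands were pooled, digested with a collagenase-based enzyme blend (Liberase) and DNase, passed through a strainer, washed and resuspended as single cells. The number of animals in each pool is not given in the sources used here. The series title names the 10x Genomics platform and the protocol names Drop-seq for the barcoding step, both of which label the RNA of each cell with a barcode in a droplet. Enzyme digestion of live tissue can induce stress genes and can favour some cell types, and both bear on the shares and levels reported.

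The deposited files hold UMI counts per gene and barcode, as whole numbers with no normalization. Per the submitters' processing notes, Cell Ranger and the mm10 genome build were used. The Cell Ranger version, its settings, the gene annotation, and how barcodes were chosen are not given in the sources used here. Such counting usually collapses reads by UMI and leaves out reads that map to several genes, so that values of near-identical paralogs are uncertain. The files list 27775 features, and 39 symbols shared by several gene identifiers (86 features) were kept apart by identifier. The 13 mitochondrial features had 0 UMIs in both libraries, so the filter on the mitochondrial share removed no barcode and dying cells could not be judged from it. Coordinates of named genes came from the GENCODE M21 annotation of the same build (GRCm38), matched on the Ensembl identifier, and 57 of 57 genes matched.

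Barcodes with at least 200 detected genes and at most 10% mitochondrial UMIs were kept, which left 259 of 437 in E16 and 406 of 687 in P4, with 1711606 and 1975814 UMIs. Scrublet, as in scanpy, called 1 doublet in each library, and these cells were kept. Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were scaled and clipped at 10, and Leiden clustering at resolution 1 was run on 20 principal components with 15 neighbours. Epithelial-like cells were then clustered within each library on 10 components.

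Clusters were named from marker genes fixed before the data were examined. A cluster took the class with the highest mean standardized expression of its markers. It stayed unnamed if fewer than 3 of these were detected in at least 20% of its cells, if more markers of another class were among its 10 leading genes, or if it was shallow with no marker among them. Leading genes were those with the largest ratio of CPM, with 20 added to both values, among genes in at least 25% of the cluster's cells. Leading genes for this check were taken against cells of clusters that scored highest for another class. The epithelial-like cluster led by Dcpp genes had 5 epithelial markers detected but none among its leading genes.

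Stages were compared within a class by summing UMIs over its cells in each library and dividing by the class total, as counts per 1000000 (CPM). The ratio of P4 over E16 has an exact conditional 95% interval, and a share has an exact Clopper-Pearson interval, both for counting error only. A gene at 0 UMIs was set to a floor of 3 counts over the class, equal to 4.77 CPM in E16 and 4.07 CPM in P4 for epithelial-like cells and 4.71 and 3.70 CPM for mesenchyme-like cells. Because each stage is 1 library, no test across samples was made and no p-value is given. Of 21 gene lists fixed before the data were examined, each was summarized by the median log2 ratio of its members with at least 30 UMIs over both libraries in the class, if it had at least 3. The median was placed among 10000 random lists matched on mean CPM in 20 bins, and its counting interval came from 200 Poisson draws. In epithelial-like cells 19 lists had a median, of which 4 lay below and 7 above the central 95% range. In mesenchyme-like cells 20 had one, of which 3 lay below and 5 above.

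Genes were named by a rule also set before the data were examined. A gene needed at least 30 UMIs in the library with the higher CPM, a UMI in at least 10% of the class's cells there, and a CPM that no class of 20 or more cells in that library exceeded by more than 3 times. Mitochondrial, ribosomal protein, haemoglobin, sex-specific and provisional gene models were left out. Genes were ranked by the interval bound nearest a ratio of 1, and the first 12 in each direction were named, apart from results that are not reported here. Of each list, up to 3 members furthest in the direction of its median and 1 furthest the other way could be named. Cells with at least 3 genes of the G2/M list were counted after thinning each cell to the 10th percentile of UMI totals of the shallower library.

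Several choices were made after values had been seen. The check of a cluster's name was first made against all other cells. Under some alternative settings this left a mesenchyme cluster unnamed because of a single adipocyte marker, Lpl, and the check against cells of other classes replaced it. It gave the same classes in the main analysis, and values under the first form are reported among the alternatives. The need for a marker among the leading genes of an epithelial sub-cluster was added after weak scores had been seen. The marker sets for salivary and tear proteins and the runs without single epithelial clusters or without erythroid-like cells were also added then, as were the counts of named genes per cell and the choice to give cluster 12 by number.

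The alternatives were all barcodes or at least 500 genes, doublets removed, resolution 0.5 or 2, each library clustered alone, cell cycle genes left out of the clustering, 10 principal components, 1000 variable genes, other scalings (CPM without the 20 most abundant and the haemoglobin and ribosomal protein genes, median ratios, cells weighted equally, thinned cells), members with at least 10 or 100 UMIs, and 2 or 5 G2/M genes. The comparison was tested on simulated data drawn from the real cells' totals and class means with known changes. In epithelial-like cells, on 4995 genes, the interval held the true ratio for 96.6% of genes, the interval excluded 1 for 96% of genes raised 2-fold and 90% of genes set to 0.5 of their level, and 2% of unchanged lists lay outside that range. In mesenchyme-like cells, on 5660 genes, the values were 96.0%, 96%, 88% and 2%. The simulated cells of a class in a library shared a single profile. These values therefore cover counting error only, not the spread between real cells or genes that vary together. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.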

Results

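Lacrimal glands make the watery part of tears, and in the mouse they branch before birth and take up secretion after it. The data set held RNA of single cells from the lacrimal glands of wild-type CD1 mice, an outbred strain, at embryonic day 16 (E16) and at postnatal day 4 (P4). Each stage was 1 library made from pooled glands. The E16 library held 437 barcodes with 2234700 UMIs (unique molecular identifiers, each standing for 1 captured transcript), and the P4 library held 687 barcodes with 2712614 UMIs. Barcodes with fewer than 200 detected genes were left out. They numbered 178 in E16 and 281 in P4, and haemoglobin transcripts made up a median of 95.9% and 95.7% of their UMIs. The 259 E16 cells kept had a median of 5802 UMIs, with a range of 852 to 31749, and the 406 P4 cells kept had a median of 3767 UMIs, with a range of 715 to 64020. With 1 library per stage there was no replicate check, so no test across samples was possible. The intervals given are 95% intervals and cover counting error only, not the spread between cells.

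The comparison of cell classes asked which cells the gland preparations held at each stage. Epithelial-like and mesenchyme-like cells were the most frequent classes in both libraries. Epithelial-like cells were 89 of 259 in E16 (34.4%, exact Clopper-Pearson interval 28.6 to 40.5%) and 98 of 406 in P4 (24.1%, 20.1 to 28.6%). Mesenchyme-like cells were 96 in E16 (37.1%, 31.2 to 43.3%) and 177 in P4 (43.6%, 38.7 to 48.6%). Macrophage-like cells, which expressed complement genes such as C1qa, were 2 in E16 (0.772%, 0.0937 to 2.76%) and 47 in P4 (11.6%, 8.63 to 15.1%). T or innate lymphoid-like cells were 0 of 259 in E16, which allows a share of up to 1.16% when 3 counts are taken as the limit of a 0, or 1.41% by the exact interval, and 18 in P4 (4.43%, 2.65 to 6.92%). That class was a single cluster with a median of 1268 UMIs, well below the P4 median. Erythroid-like cells made up 9.65% (6.34 to 13.9%) of kept cells in E16 and 2.96% (1.54 to 5.11%) in P4. The filter on genes per barcode had left out 178 of 437 barcodes in E16 and 281 of 687 in P4. Haemoglobin made up a median of 95.9% and 95.7% of the UMIs of these barcodes. The erythroid-like shares therefore depend on that filter and do not give the frequency of red cells in the preparations. Cluster 12, with 16 E16 and 9 P4 cells, scored highest for pericyte markers, but only Rgs5 of these was among its 10 leading genes, against 5 smooth muscle genes (Actg2, Tagln, Acta2, Cnn1 and Myh11), so it is given by number and its share was not compared. Endothelial-like cells numbered 10 and 22, mast-like cells 9 and 4, and glial-like cells 6 and 4. A cluster led by Cd74, Ctss and Lyz2, with 6 E16 and 15 P4 cells, stayed unnamed. Dissociation and droplet capture can set these shares, as can the difference in depth between the libraries. Shares of all classes also depend on the filter on genes per barcode and on the choices in clustering and naming. The P4 epithelial-like share was 12.6% with each library clustered alone. With at least 500 genes and cluster names checked against all cells, the epithelial-like shares were 17.1% in E16 and 19.1% in P4, in the reverse order. With cluster names checked against all cells, the P4 mesenchyme-like share was 22.9% without cell cycle genes and 23.4% with 1000 variable genes, below the E16 shares of 32.8% and 35.9%, so the order of the stages was not kept.

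**Figure D1:**
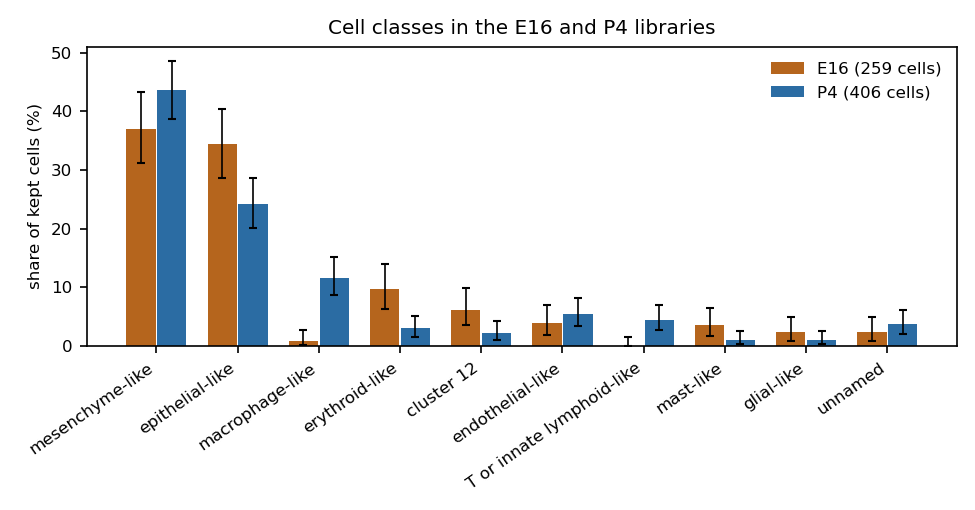
Share of kept cells (vertical axis, %) in each cell class (horizontal axis) for the E16 library (259 cells, brown bars) and the P4 library (406 cells, blue bars), with exact 95% Clopper-Pearson intervals as error bars. Macrophage-like cells made up 0.772% of E16 and 11.6% of P4 cells. Cluster 12 held pericyte and smooth muscle genes.

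Epithelial-like cells were compared between the stages by summing their UMIs, which gave 628734 in E16 and 736613 in P4. The genes with the largest ratios encode secreted proteins and were near or at 0 UMIs in E16. Dcpp1, Dcpp2 and Dcpp3, which encode demilune cell and parotid proteins, had 73249, 50517 and 39511 UMIs in P4 and 19, 1 and 0 in E16. Together with Smgc, a secreted protein of the neonatal submandibular gland, they made up 237248 counts per 1000000 UMIs (CPM) of P4 epithelial-like cells. Dcpp1 was higher in P4 by 3291-fold (2107 to 5466). Smgc, with 11483 UMIs against 0, was 3267-fold higher, taking 3 counts over the class as the floor for a 0. For genes at 0 the exact interval has a smaller lower bound, which was 2657-fold for Smgc. Bpifa2, a salivary secretory protein also called Psp, was 1863-fold higher at that floor (6549 UMIs against 0, lower bound 1515). Prol1, which encodes a proline-rich lacrimal protein, had 3383 UMIs in P4 and 0 in E16 and was 963-fold higher at the floor (lower bound 782).

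These class sums rested on few cells. A P4 sub-cluster of 10 of the 98 epithelial-like cells held 72203 of the Dcpp1, 50389 of the Dcpp2 and 39461 of the Dcpp3 UMIs, and the cell with the most UMIs held 33.4%, 36.1% and 37.3% of them. In the other 88 cells Dcpp1 stood at 2004 CPM, Dcpp2 at 245 CPM and Dcpp3 at 95.8 CPM. For Dcpp2 and Dcpp3 this was near the 284 and 84.7 CPM of P4 cells outside the epithelium, so that their class values describe the sub-cluster. Of the Prol1 UMIs 3356 came from a single cell, and 1 cell each held 51.02% of the Bpifa2, 53.3% of the Scgb2b27 and 66.8% of the Scgb2a2 UMIs. The 10 cells with the most UMIs held 99.2% of the Smgc, 97.02% of the Mucl2, 93.1% of the Scgb2b2, 79.9% of the Esp6 and 71.7% of the Pip UMIs. The ratios of these genes therefore describe few cells, and their intervals treat UMIs as independent.

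Further P4 transcripts belonged to families of tear and exocrine gland proteins. The secretoglobins Scgb2b2, Scgb2b27 and Scgb2a2 had 735, 591 and 217 UMIs in P4 and 0 in E16. At the floor they were 209-fold, 168-fold and 61.7-fold higher (lower bounds 170, 136 and 49.8). Pip (339 UMIs) and the mucin-like gene Mucl2 (302 UMIs) were likewise at 0 in E16. Their ratios at the floor were 96.5-fold and 85.9-fold (lower bounds 78.0 and 69.5). Esp6, of the exocrine gland-secreted peptide family, had 996 UMIs in P4 and 6 in E16 and was 142-fold higher (64.9 to 387). On the mm10 build, Dcpp1 (ENSMUSG00000096445) lies on chromosome 17 from 23880876 to 23882853, Dcpp2 (ENSMUSG00000096278) from 23880880 to 23900788 and Dcpp3 (ENSMUSG00000057417) from 23917458 to 23919441, all on the plus strand. The annotated spans of Dcpp1 and Dcpp2 overlap and the genes are paralogs, so reads may have been split uncertainly among them. Smgc (ENSMUSG00000047295) lies on chromosome 15 from 91838265 to 91861438, and Prol1 (ENSMUSG00000064156) on chromosome 5 from 88317312 to 88328814.

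Secretory transcripts were also present in P4 cells outside the epithelium, at lower levels than in the class sum. Dcpp1 was detected in 79.9% of the 308 other P4 cells, with a median depth of 3821.5 UMIs, and in 74.5% of P4 epithelial-like cells, with a median depth of 3371 UMIs. Its level was 459 CPM outside the epithelium, 99440 CPM over all P4 epithelial-like cells and 2004 CPM in the 88 of them outside the sub-cluster led by Dcpp genes. Detection of a Dcpp1 UMI in a single P4 cell therefore did not separate epithelial-like cells from others. In E16, Dcpp1 was detected in 11 of the 89 epithelial-like cells and in 0 of the 170 other cells.

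The genes named as higher in E16 epithelial-like cells had at most 177 UMIs there. Has2, a hyaluronan synthase, had 82 UMIs against 0 and was 32.02-fold higher in E16 at the floor (lower bound 25.5). Crispld2 had 98 UMIs against 1 (115-fold, 20.1 to 4581), Sema3b, a secreted semaphorin, 114 against 2 (66.8-fold, 18.1 to 558), and Fabp7, a fatty acid binding protein, 177 against 5 (41.5-fold, 17.4 to 129). The amino acid transporter Slc7a5 was 30.7-fold higher (12.8 to 96.1) and the membrane glycoprotein Pdpn 23.3-fold higher (11.5 to 54.9). The replication-dependent histone gene Hist1h2ae was 23.0-fold higher (11.9 to 51.2). Rasl11b, Plcl1, Homer1 and Hist1h2an were also named in this direction, but 1 cell held 68.3% of the Plcl1 and 75% of the Homer1 UMIs. The 10 E16 cells with the most UMIs held 80.5% of the Rasl11b, 79.2% of the Hist1h2an, 72.4% of the Crispld2, 68.9% of the Hist1h2ae, 68.3% of the Has2, 64.04% of the Sema3b, 58.8% of the Fabp7, 58.5% of the Pdpn and 48.1% of the Slc7a5 UMIs, so that these values also rested on part of the class. The clusters behind these values differed between the libraries. E16 epithelial-like cells came from clusters 2 (51 cells), 10 (30) and 6 (8), and P4 cells from clusters 6 (34), 2 (33), 11 (28) and 10 (3). The Dcpp genes, Prol1, Smgc, Scgb2b27, Bpifa2 and Mucl2 also led cluster 11, which held P4 cells only, Crispld2 was among the leading genes of cluster 10, and Fabp7 among those of cluster 2.

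**Figure D2:**
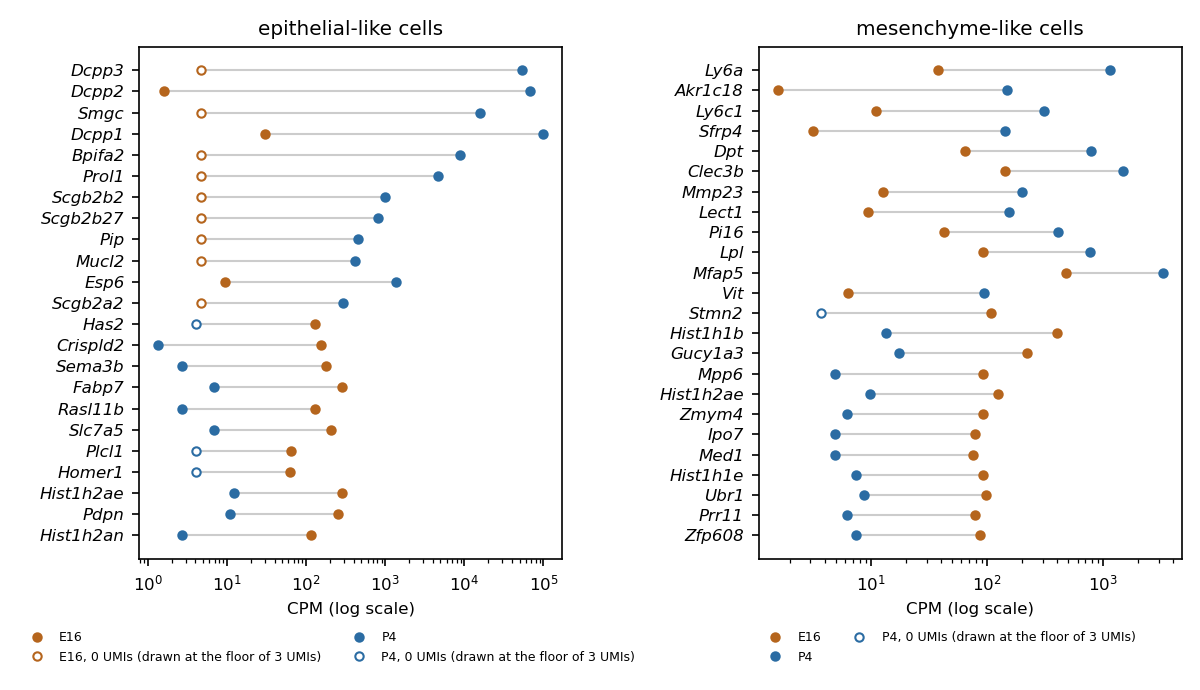
CPM, counts per 1000000 UMIs (horizontal axis, log scale) of the genes named for epithelial-like cells (left) and for mesenchyme-like cells (right) in E16 (brown) and P4 (blue), where an open circle marks 0 UMIs and is drawn at the floor of 3 UMIs. The widest gaps were those of secretory genes in epithelial-like cells, such as Dcpp1 with 30.2 CPM in E16 and 99440 CPM in P4, a value set by 10 of the 98 cells.

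Gene lists fixed before the data were examined placed these genes among wider groups. Each list's median log2 ratio of P4 over E16 was set among the medians of 10000 random lists of the same size matched on mean CPM, as a description of these libraries. Because the secretory transcripts took so much of the P4 total, the median of all 5014 measured genes was -0.53 in epithelial-like cells, and -0.08 when the most abundant genes were left out of the totals. List medians are therefore also given relative to that of all measured genes. The lacrimal secretory list had a median of 3.54 (counting interval 3.09 to 4.02), 4.07 relative to all genes, and lay at percentile 100. Of its 19 measured members 15 were at least 2-fold higher in P4 and 1 at least 2-fold lower, which became 17 and 1 with the most abundant genes left out. Members at 0 UMIs in 1 library entered at the floor. With cells weighted equally the median was 3.72. Prol1, Scgb2b2 and Car6, a secreted carbonic anhydrase, were furthest up, and Lcn2 was 2.78-fold higher in E16. Car6 rested on few cells, since 621 of its 705 UMIs came from a single P4 cell and the rest from 5 others.

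Genes of luminal and duct epithelium were also higher in P4. That list had a median of 0.61, 1.13 relative to all genes, at percentile 100, with 7 of 16 members at least 2-fold higher and 1 lower. The keratin genes Krt7 and Krt18 were higher by 7.77-fold (4.88 to 13.0) and 4.42-fold (3.998 to 4.89), and the tight junction gene Cldn3 by 3.78-fold (3.04 to 4.74), while Cldn6 was 7.11-fold higher in E16 (4.02 to 13.6). The endoplasmic reticulum and secretory pathway list lay at percentile 100 with a median of 0.26, or 0.79 relative to all genes. It did not keep its place above the range under 1 of 26 alternatives, the run without the Dcpp-led cluster 11, which held P4 cells only. Of its 30 members 4 were at least 2-fold higher and 8 lower, against 9 higher and 1 lower with the most abundant genes left out. Sec11c, a signal peptidase subunit, was 8.57-fold higher (5.72 to 13.4) and Herpud1 2.85-fold higher (1.97 to 4.21). The myoepithelial and smooth muscle list had a median of 0.13 at percentile 98.22, with Cnn1 (calponin) at 65 UMIs against 2 and Mylk at 44 against 9, but it lay inside the range under 14 of 26 alternatives and had a median of -0.19 when only members with at least 100 UMIs were used.

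Glycolysis and hypoxia genes formed the list furthest down in P4 epithelial-like cells. Its median was -2.01 (-2.15 to -1.80), or -1.48 relative to all genes, below all 10000 random lists. Of 16 measured members 14 were at least 2-fold lower in P4 and 1 higher, and 12 and 1 with the most abundant genes left out. The lactate transporter Slc16a3 had 39 UMIs in E16 and 1 in P4 (45.7-fold higher in E16, 7.73 to 1850), the collagen prolyl hydroxylase P4ha1 50 and 2 (29.3-fold, 7.70 to 249), and the glucose transporter Slc2a1 70 and 9 (9.11-fold, 4.54 to 20.8). Hk1 went the other way, with 10 UMIs in E16 and 35 in P4. The summed list stood at 10846 CPM in E16 and 2936 CPM in P4, a ratio of 0.271 (0.258 to 0.284).

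**Figure D3:**
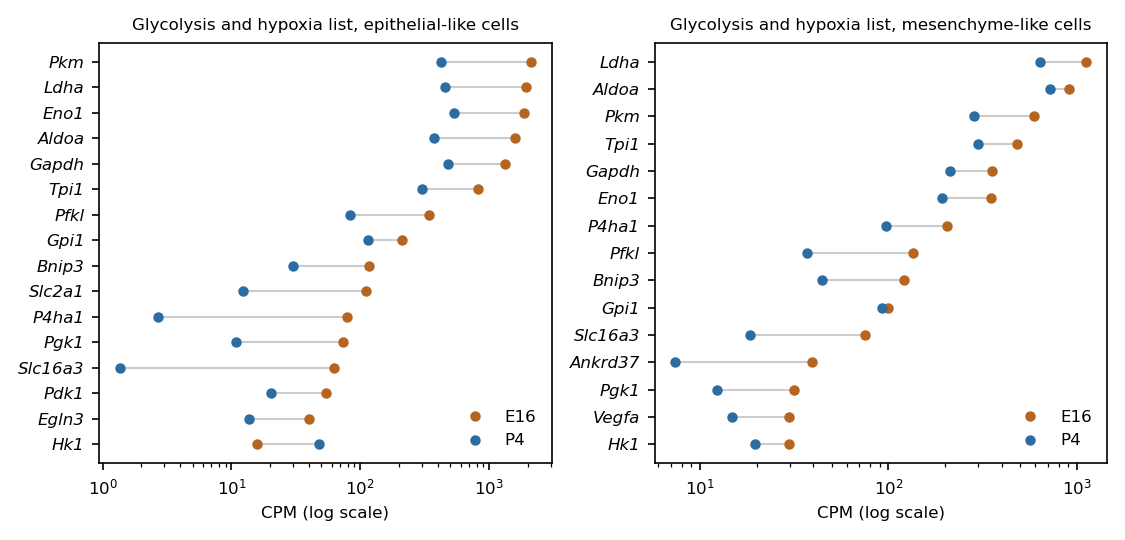
CPM, counts per 1000000 UMIs (horizontal axis, log scale) of each measured member of the glycolysis and hypoxia list in epithelial-like cells (left, 16 genes) and mesenchyme-like cells (right, 15 genes) in E16 (brown) and P4 (blue). In epithelial-like cells 14 of the 16 members were at least 2-fold lower in P4.

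Other lists lay lower in P4 epithelial-like cells, on few measured members. The FGF and growth factor list had a median of -1.27 (-0.74 relative to all genes, percentile 1.65, 6 members), with the heparin-binding factors Ptn and Mdk 3.18-fold (2.58 to 3.94) and 3.08-fold (2.66 to 3.57) higher in E16 and Kitl 1.99-fold higher in P4 (1.06 to 3.93). The basement membrane list had a median of -1.33 (-0.80 relative to all genes, percentile 2.18, 6 members), and Smoc2 was 7.86-fold higher in E16 (4.70 to 13.96). With the most abundant genes left out its median of -0.88 lay inside the range of random lists. The lipid and adipogenic list had a median of -1.17 (-0.65 relative to all genes, percentile 1.995, 9 members), and Fabp5 was 9.02-fold higher in E16 (6.62 to 12.5). These 3 lists did not keep their place below the range under 5 of 25, 5 of 24 and 16 of 26 alternatives, in this order. Basal keratin and hemidesmosome genes lay inside the range of the random lists at percentile 4.735, with a median of -1.07 over 9 members. Among them Krt15 was 18.6-fold higher in E16 (9.16 to 44.0) and Trp63, a basal cell transcription factor, 3.95-fold (1.75 to 10.1). Regulators of lacrimal budding had a median of -0.62 at percentile 37.58, within which the FGF-responsive factors Etv5 and Etv4 were 14.3-fold (7.73 to 29.3) and 11.3-fold (4.90 to 32.1) higher in E16 and Foxc1 2.56-fold higher in P4 (1.30 to 5.41).

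The fibrillar matrix list lay at percentile 100 in epithelial-like cells as well, with a median of 0.59, and at -0.97 when only members with at least 100 UMIs were used. The source of these transcripts was not tested. Col1a1 stood at 49.3 CPM in E16 and 191 CPM in P4 epithelial-like cells, against 107 CPM in P4 endothelial-like and 122 CPM in P4 macrophage-like cells, and it was detected in 38.8% of P4 epithelial-like cells (median depth 3371 UMIs) and 31.9% of P4 macrophage-like cells (median depth 2887 UMIs). The antigen presentation and interferon list had a median of 0.42 at percentile 99.14, with Ifi27 3.87-fold higher in P4 (2.19 to 7.29) and Ifitm3 4.67-fold higher in E16 (4.07 to 5.38), and a median of -0.18 with members of at least 100 UMIs. The immediate early and heat shock list had a median of -0.12, which is 0.40 relative to all genes, at percentile 98.745, and its sign depended on the scaling. Cell cycle lists did not stand apart in epithelial-like cells. The S phase and G2/M medians were -0.66 and -0.65, at percentiles 24.18 and 22.03. Oxidative phosphorylation genes had a median of -0.50 at percentile 52.56, BMP and TGF-beta genes -1.08 at 7.63, imprinted growth genes -0.86 at 9.895 and adult fibroblast genes -0.74 at 23.48. The Wnt and hedgehog lists had 2 measured members each and were given no median.

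**Figure D4:**
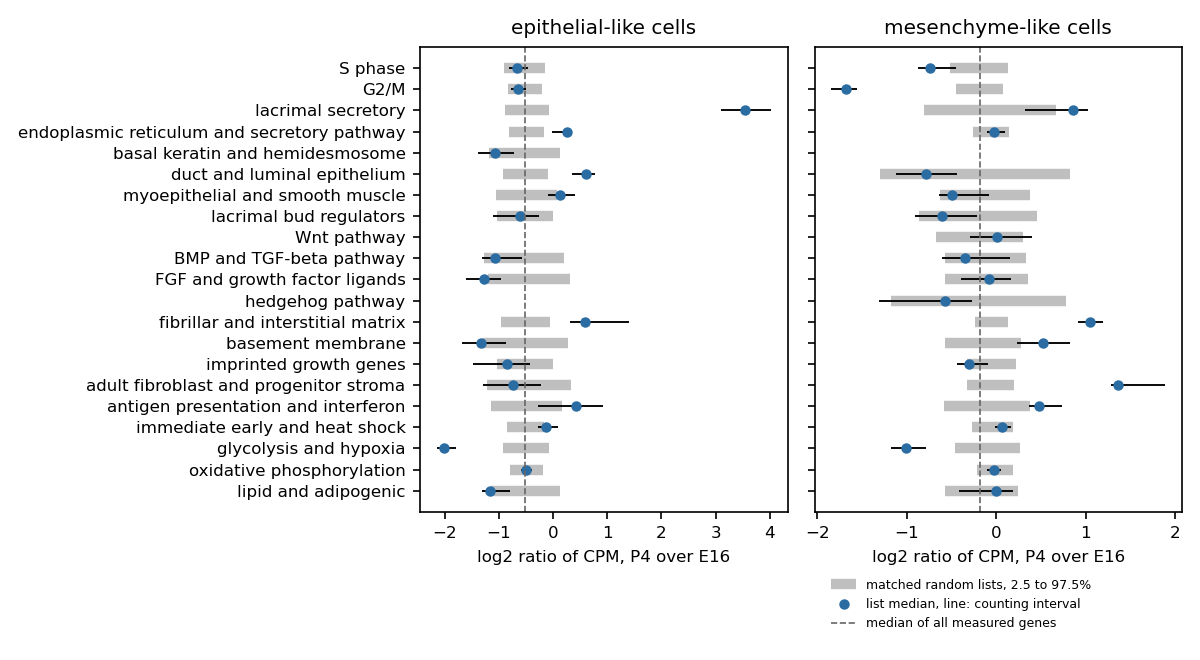
Median log2 ratio of CPM in P4 over E16 (horizontal axis) for each gene list (vertical axis) in epithelial-like cells (left) and mesenchyme-like cells (right). Points are list medians with their counting intervals, grey bars the central 95% range of 10000 matched random lists and the dashed line the median of all measured genes. The lacrimal secretory list stood at 3.54 and the glycolysis and hypoxia list at -2.01 in epithelial-like cells.

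Epithelial-like cells were also clustered within each library to describe their subtypes. In P4, a myoepithelial-like group of 17 of 98 cells (17.3%, 10.4 to 26.3%) was led by Lamb1, Acta2, Ccdc90b, Ccdc23 and Id4. A duct-like group of 15 cells (15.3%, 8.82 to 24.0%) was led by Sftpd, Nupr1, Cyp2f2, Krt19 and Esp18, and the acinar marker Ltf was also among its leading genes. The P4 groups led by Sftpc (17 cells), by Scgb2a2 and Mucl2 (16 cells) and by Dcpp3 (10 cells), and a group of 23 cells, carried no marker among their leading genes and stayed unnamed. In E16, a duct-like group of 12 of 89 cells (13.5%, 7.17 to 22.4%) was led by Wfdc18, Adh7, Cldn4, Krt19 and Nupr1, of which Wfdc18 is an acinar marker. The other 4 E16 groups stayed unnamed.

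In mesenchyme-like cells, 636844 UMIs in E16 were compared with 811802 in P4. Genes of surface and matrix proteins typical of adult connective tissue were higher in P4. Ly6a, which encodes the surface antigen Sca-1, was 30.3-fold higher (20.2 to 47.5, 927 UMIs against 24), and Ly6c1 28.1-fold higher (13.5 to 70.7). The matrix protein gene Dpt (dermatopontin) was 12.1-fold higher (8.84 to 17.1), Clec3b (tetranectin) 10.4-fold (8.42 to 13.0), Pi16 9.50-fold (6.41 to 14.6), the lipoprotein lipase gene Lpl 8.24-fold (6.30 to 11.0) and the microfibril gene Mfap5 6.83-fold (6.06 to 7.71). Sfrp4, a secreted Wnt antagonist, had 115 UMIs against 2 (45.1-fold, 12.2 to 377), and Akr1c18 had 119 against 1 (93.4-fold, 16.4 to 3718). Mmp23, Lect1 and Vit were higher by 15.8-fold, 16.3-fold and 14.9-fold. The 10 P4 cells with the most UMIs held 82.4% of the Akr1c18, 69.6% of the Lect1, 65.2% of the Sfrp4, 55.05% of the Pi16 and 48.7% of the Vit UMIs, and 19.9% to 38.6% of those of the other 7 genes. Ly6a (ENSMUSG00000075602) lies on chromosome 15 from 74994877 to 74998031, and Dpt (ENSMUSG00000026574) on chromosome 1 from 164796644 to 164824266.

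Several of the genes higher in E16 mesenchyme-like cells are linked to cell division. The linker histone gene Hist1h1b had 254 UMIs against 11 (29.4-fold, 16.2 to 59.7), and Hist1h2ae and Hist1h1e were 12.6-fold (6.09 to 30.2) and 12.3-fold (5.33 to 34.95) higher. Hist1h2ae reversed with 10 principal components, to a log2 ratio of 0.071, or 0.92 with names checked against all cells. Stmn2, which encodes a tubulin-binding protein best known from neurons, had 69 UMIs against 0 and was 29.3-fold higher at the floor (lower bound 23.2). The 10 E16 cells with the most UMIs held 92.1% of the Hist1h1b, 92.4% of the Hist1h2ae, 82.8% of the Hist1h1e, 91.3% of the Stmn2 and 58.99% of the Gucy1a3 UMIs. Gucy1a3, a subunit of soluble guanylate cyclase, was 12.7-fold higher (7.29 to 23.8). Mpp6, Zmym4, Ipo7, Med1, Ubr1, Prr11 and Zfp608 were higher in E16 by 11.3-fold to 18.5-fold, but 1 cell each held 54% (Prr11) to 77.6% (Zmym4) of their UMIs. The E16 cells came mostly from clusters 3 (55 cells), 7 (23) and 1 (13), with 5 more in clusters 9 and 5, and the P4 cells from clusters 1 (81), 5 (42), 9 (33), 7 (14) and 3 (7). Pi16, Sfrp4, Ly6a, Dpt, Mfap5 and Ly6c1 were leading genes of cluster 5, which held 2 E16 and 42 P4 cells, Clec3b, Ly6a and Mfap5 of cluster 9, Lect1 of cluster 1, Gucy1a3 of cluster 3 and Prr11 of cluster 7.

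Lists of fibroblast and matrix genes lay higher in P4 mesenchyme-like cells. The median of all 5702 measured genes was -0.18, and -0.09 with the most abundant genes left out. The adult fibroblast and progenitor stroma list had a median of 1.36 (1.28 to 1.89), or 1.54 relative to all genes, at percentile 100, and 13 of 20 members were at least 2-fold higher in P4. Smoc2 went the other way and was 2.68-fold higher in E16 (2.06 to 3.51). The fibrillar and interstitial matrix list had a median of 1.05 (0.91 to 1.19), or 1.23 relative to all genes, at percentile 100, with 18 of 36 members at least 2-fold higher and 1, the collagen cross-linking enzyme gene Lox, at least 2-fold lower. Mfap5, the elastic fibre gene Fbln5 (6.35-fold, 4.06 to 10.4) and Loxl1 (5.78-fold, 4.28 to 7.96) were furthest up. Basement membrane genes had a median of 0.52 at percentile 99.84, with Hspg2 (perlecan) 3.09-fold higher (2.07 to 4.74). That median was -0.026 to -0.0062 under 3 alternative settings that left P4 mesenchyme clusters unnamed.

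Genes of the G2 and M phases were lower in P4 mesenchyme-like cells. The list had a median of -1.68 (-1.84 to -1.56), or -1.50 relative to all genes, below all 10000 random lists, and 33 of 36 members were at least 2-fold lower. Bub1b, Kif11 and Ccna2, which encode a mitotic checkpoint kinase, a spindle motor and cyclin A2, were 8.60-fold (2.998 to 33.8), 7.93-fold (3.89 to 18.2) and 6.47-fold (3.54 to 12.8) higher in E16. The median was 0.42 with each library clustered alone and 0.40 with 10 principal components, settings under which the glial-like share in E16 was 11.2% and 11.97% instead of 2.32%. The S phase list had a median of -0.74 at percentile 0.08, inside the range under 8 of 24 alternatives, with Rrm2 4.11-fold higher in E16 (3.19 to 5.34). After thinning to 2269 UMIs per cell, at least 3 G2/M genes were detected in 42 of 95 E16 cells (44.2%, 34.0 to 54.8%) and 27 of 159 P4 cells (17.0%, 11.5 to 23.7%), with 1 and 18 shallower cells left out. Unthinned shares were 69.8% and 30.5%. These mesenchyme shares used the main classes and were not counted under the settings in which the median changed sign. Cluster 7, with 23 E16 and 14 P4 cells, had Anln, Aurkb and Hmmr of the G2/M list among its leading genes. Whether its cells are called mesenchyme-like therefore bears on the shares. In epithelial-like cells thinned to 979 UMIs, the shares were 48 of 86 (55.8%, 44.7 to 66.5%) and 36 of 88 (40.9%, 30.5 to 51.9%), with 3 and 10 cells left out, and 76.4% and 70.4% unthinned. With at least 2 genes the thinned epithelial shares were 67.4% (56.5 to 77.2%) and 51.1% (40.2 to 61.9%), and with at least 5 genes 39.5% (29.2 to 50.7%) and 30.7% (21.3 to 41.4%). The difference was not tested. Among erythroid-like cells, which should lack these transcripts, the shares at the depth of 2269 UMIs were 0 of 25 in E16 and 1 of 12 in P4 (8.33%), with median depths of 6700 and 5439 UMIs before thinning. Free RNA in such calls stayed open.

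Glycolysis and hypoxia genes were lower in P4 mesenchyme-like cells too, by less than in the epithelium. The median was -1.01 (-1.17 to -0.79), or -0.83 relative to all genes, below all 10000 random lists, with 8 of 15 members at least 2-fold lower, and 5 with the most abundant genes left out. Ankrd37, a hypoxia-inducible gene, was 5.31-fold higher in E16 (2.13 to 15.8), Slc16a3 4.08-fold (2.25 to 7.84) and Pfkl, a phosphofructokinase, 3.65-fold (2.39 to 5.74). The summed list had a P4 over E16 ratio of 0.581 (0.550 to 0.614) in mesenchyme-like and 0.751 (0.647 to 0.869) in endothelial-like cells. Its ratio was 1.22 (0.988 to 1.503) in cluster 12 and 0.7504 (0.295 to 1.70) in erythroid-like cells, both with intervals that include 1. The antigen presentation and interferon list lay at percentile 99.02 with a median of 0.48, and the lacrimal secretory list, with 4 measured members, at percentile 98.96, though inside the range under 3 of 24 and 11 of 23 alternatives. The 12 other lists with a median lay inside the central 95% range of random lists. They included oxidative phosphorylation (-0.03), endoplasmic reticulum (-0.03), Wnt (0.0046), hedgehog (-0.57), BMP and TGF-beta (-0.35), FGF and growth factor (-0.09), imprinted growth (-0.30), lipid (-0.0044), immediate early (0.06), bud regulator (-0.61), myoepithelial (-0.50) and duct (-0.79) genes. Basal keratin genes had 1 measured member. No other class had 20 cells in both libraries, so none was compared gene by gene.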

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

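The tests on the immediate early list and on P4 reads in the E16 library, and the runs without single epithelial clusters, were chosen after the results were seen. The barcodes left out for having fewer than 200 genes carried a signal that no comparison used. In them, Hbb-bs and Hbb-bt, the adult beta-globin genes on chromosome 7, made up 84.7% and 15.3% of beta-globin UMIs in E16 and 90.8% and 9.21% in P4. The embryonic gene Hbb-y had 0 UMIs in both libraries, against 230029 of Hbb-bs in the 178 E16 barcodes and 343213 in the 281 P4 barcodes. Hbb-bs and Hbb-bt are near-identical, so reads may have been split uncertainly between them.

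The lower glycolysis and hypoxia list in P4 epithelial-like cells was weighed against technical explanations. The large secretory share of the P4 total was argued against as the whole cause by the median of -1.58 without the Dcpp-led cluster, and the epithelial cluster of lowest median depth by the median of -2.17 without it. That last run compared 30 cells of cluster 10 and 8 of cluster 6 in E16 with 34 of cluster 6, 28 of cluster 11 and 3 of cluster 10 in P4. Its size may therefore also reflect which clusters each library held. A single factor acting equally on all cells was argued against as the whole cause by ratios of the summed list whose intervals lay apart. These ratios were 0.271 in epithelial-like, 0.581 in mesenchyme-like and 0.751 in endothelial-like cells. In cluster 12 the ratio was 1.22 (0.988 to 1.503) on 16 E16 and 9 P4 cells of mixed pericyte and smooth muscle genes. The intervals cover counting error only, and a shared factor acting unequally on the classes was not tested. Erythroid-like cells had 0.7504 (0.295 to 1.70) on 27 and 8 UMIs, so that 4 of 5 classes were lower, and a smaller lowering shared by all cells stays open. A stronger handling response in E16 also stays open. The lower percentile of the immediate early and heat shock list in both classes, 82.46, lay inside the range of random lists, as did the bound first set for it, and in epithelial-like cells the list lay at 98.745, above that range and against the explanation, or at 72.7 with cells weighted equally. Its epithelial members went both ways, 2 at least 2-fold higher in P4 and 3 lower, or 5 and 2 with the most abundant genes left out. Hsph1, Hsp90aa1 and Klf2 were furthest down in P4, and Jund was furthest up. Hsph1 and Hsp90aa1 were higher in E16 by 6.80-fold (2.60 to 22.5) and 2.92-fold (2.45 to 3.49). These ratios are not relative to all measured genes, whose median log2 ratio was -0.53. Different epithelial sub-populations in the libraries stay open, since within cluster 6 the ratio was 0.754 (0.652 to 0.876) and within cluster 2 it was 0.495 (0.445 to 0.550), and the list may therefore be lower for both reasons, with developmental stage untested.

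Secretory transcripts in P4 cells outside the epithelium were set against free RNA, and the few such UMIs in E16 cells against misassigned P4 reads. Free RNA from secretory cells stays a candidate explanation: the share of Dcpp1 among Dcpp1, Dcpp2, Dcpp3 and Smgc differed by a factor of 1.5 between P4 classes outside the epithelium with at least 30 UMIs of them, from 33.3% to 50%. Classes with fewer were left out of that factor. They were T or innate lymphoid-like cells at 34.6% of 26 UMIs, glial-like cells at 50% of 22 and mast-like cells at 71.4% of 7 (29.04 to 96.3%), which is 2.14 times the lowest share. The intervals overlapped, so these values decided nothing. Dcpp3 made up 22.6% of the 4 genes' UMIs in P4 epithelial-like cells, nearly all in a sub-cluster of 10 cells, and 8.51% (6.72 to 10.6%) in mesenchyme-like cells, a difference that 1 source with the mean epithelial makeup would not give and that a source richer in the other genes could. P4 reads assigned to the E16 library could not explain transcripts in P4 cells, so their test bears only on the E16 UMIs. There such reads were argued against as the whole source. Dcpp1 made up 95% (75.1 to 99.9%) of the UMIs of these 4 genes and Bpifa2 in E16, and 40.4% in P4. The E16 value rests on 19 Dcpp1 and 1 Dcpp2 UMIs. Reads exchanged between barcodes within the P4 library were not tested.

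Salivary-type transcripts, such as the Dcpp genes, Smgc and Bpifa2, could come from cells of another gland in the P4 preparation. Of 17 P4 epithelial-like cells with the salivary set at 10 times its level outside the epithelium, 10 (58.8%, 32.9 to 81.6%) also had the tear set at 10 times its own, and 51 of all 98 did. The interval reached from below to above 50%, so another gland stays open. Scgb2b27, the tear set member highest in the cells high in the salivary set, also led cluster 11 together with the Dcpp genes, as did Mucl2. Finding both sets in a cell may therefore not tell the glands apart. The most abundant genes of the salivary-high cells were Dcpp1 at 249724 CPM and Dcpp2 at 172993 CPM. Of the tear set, Scgb2b27 stood there at 1935 CPM, Mucl2 at 422, Pip at 374, Esp6 at 326, Lpo at 168, Scgb2b2 at 3.43 and Scgb2a2 at 0 CPM, against 802, 410, 460.2, 1352, 201, 998 and 295 CPM over all P4 epithelial-like cells. Of the parotid genes, Amy1 had 0 UMIs and Prpmp5 355 UMIs in P4 epithelial-like cells, and Prb1, Prh1 and Cst10 had 11, 3 and 4. In the salivary-high cells Prpmp5 stood at 1177 CPM, Prb1 at 37.7, Prh1 at 10.3 and Cst10 at 13.7 CPM. Over all P4 epithelial-like cells they stood at 482, 14.9, 4.07 and 5.43 CPM. Like the Dcpp genes, these parotid genes were thus higher in the salivary-high cells, which goes with another gland but does not show it. No sort or gate that would remove such cells is given in the sources used here.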

How the results depend on the processing

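The runs that check cluster names against all cells and those without single epithelial clusters were chosen after the results were seen. No paired analysis was possible because each stage is 1 library and no result comes from a test. Of 576 values of the 24 named epithelial genes under alternatives 0 changed direction, and of 528 of the 24 mesenchyme genes 2 did, both of Hist1h2ae. These genes were picked for the most extreme ratios in these same libraries, so few changes could arise and the counts say little about other genes. Over all alternatives the lacrimal secretory median in epithelial-like cells ranged from 3.20 to 5.05, the glycolysis median from -2.17 to -1.16 there and from -1.29 to -0.80 in mesenchyme-like cells, the fibrillar matrix median in mesenchyme-like cells from 0.92 to 1.47 and the adult fibroblast median from 1.36 to 2.53. The G2/M medians did not keep their direction, ranging from -0.76 to 0.017 in epithelial-like and from -1.70 to 0.74 in mesenchyme-like cells. Where no cause is named below, the cause was not tested.

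With all barcodes kept, the epithelial-like shares were 19.9% in E16 and 14.3% in P4 and the mesenchyme-like shares 17.6% and 25.04%, and the mesenchyme G2/M median was -0.25. With each library clustered alone, the P4 epithelial-like share was 12.6% and the E16 mesenchyme-like share 30.5%. The epithelial medians were then -0.28 for G2/M, 4.10 for secretory, 0.44 for immediate early and -1.61 for glycolysis genes, and the mesenchyme G2/M median was 0.42. These 7 values were the same with names checked against all cells. With 10 principal components the E16 mesenchyme-like share was 28.6%, the mesenchyme G2/M median 0.40 and Hist1h2ae 0.071.

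In epithelial-like cells, scaling without the most abundant genes gave -0.21 for G2/M, 0.32 for immediate early and -1.56 for glycolysis genes, and median-ratio scaling gave -0.12, 0.41 and -1.47, and 4.08 for secretory genes. Cells weighted equally gave -0.13 for G2/M and -1.54 for glycolysis, and thinned cells 0.017 for G2/M, 0.23 for immediate early and -1.16 for glycolysis genes. In mesenchyme-like cells median-ratio scaling gave -1.50 for G2/M and 1.23 for fibrillar matrix, and thinned cells -1.52 for G2/M. Members with at least 100 UMIs gave epithelial medians of 5.05 for secretory, -0.19 for myoepithelial, -0.97 for fibrillar matrix and -0.18 for antigen presentation genes, over fewer genes by construction. Without the Dcpp-led cluster the medians were -0.15 for G2/M, 0.37 for immediate early and -1.58 for glycolysis genes, and without the shallow cluster -0.54 for myoepithelial and -2.17 for glycolysis genes.

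Checking names against all cells moved further values. With all barcodes the shares were 19.9% and 14.3% for epithelial-like and 16.7% and 13.2% for mesenchyme-like cells in E16 and P4, and the mesenchyme medians were 0.066 for G2/M, 1.22 for fibrillar matrix and 2.53 for adult fibroblast genes. With at least 500 genes the epithelial-like shares were 17.1% and 19.1% and the P4 mesenchyme-like share 13.9%, the epithelial myoepithelial median -0.59, and the mesenchyme medians -0.64 for G2/M, 1.47 for fibrillar matrix, -0.023 for basement membrane, 2.03 for adult fibroblast and -1.29 for glycolysis genes. The P4 mesenchyme-like share was 23.5% with doublets removed, 30.5% at resolution 2, 22.9% without cell cycle genes, 23.4% with 1000 variable genes and 24.1% with 10 components, where the E16 share was 23.9%. The mesenchyme G2/M median was -1.22, -1.42, -1.21, -1.27 and 0.74 in these settings. Fibrillar matrix was 1.34 with doublets removed and 1.39 without cell cycle genes, and basement membrane -0.0062 and -0.026. Adult fibroblast was 1.91 without cell cycle genes and 2.45 with 10 components, where Hist1h2ae was 0.92. Of the other list medians under alternatives 133 moved beyond their counting interval and 627 did not. A change of sign was counted apart only for lists outside the range of random lists, so the 133 may include changes of sign. Depth limits these comparisons most for genes near the floor of 3 UMIs.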

Other observations

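The P4 epithelial-like cells differed among themselves in which secreted proteins they carried. Of the 17 cells with the salivary set at 10 times its level outside the epithelium, 8 were in the group led by Dcpp genes and 4 in that led by Scgb2a2 and Mucl2. Of the 51 cells with the tear set at 10 times its own, 14 were in the group led by Sftpc, 13 in that led by Scgb2a2 and Mucl2, and 5 in that led by Dcpp genes. The level outside the epithelium was 67.8 CPM for the tear set and 1072 CPM for the salivary set. A few UMIs could therefore make a cell high in the tear set. Median depth also differed, with 12875, 3143 and 9487 UMIs in the groups led by Sftpc, by Scgb2a2 and Mucl2, and by Dcpp genes. In cells high in both sets, the salivary set made up a median of 58.9% and the tear set 0.264% of a cell's UMIs. Both sets were chosen after the data were examined, and genes of both had UMIs in some P4 cells outside the epithelium.

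Single genes of the imprinted list differed between the stages, while the list as a whole lay inside the range of random lists in both classes (percentiles 9.895 and 3.655), though not under 11 of 25 and 5 of 24 alternatives. Grb10, an adaptor that dampens insulin signalling, was 14.1-fold higher in E16 in epithelial-like cells (6.53 to 36.0) and 1.54-fold in mesenchyme-like cells (1.26 to 1.87). Igf2bp3 was higher in E16 by 3.97-fold (2.098 to 8.02) and 3.19-fold (1.67 to 6.41) and Igf2bp2 by 9.67-fold (3.44 to 37.6) and 2.63-fold (1.38 to 5.25). The list was not limited to imprinted genes, and Igf2bp2 and Igf2bp3 are among its members that are not imprinted. Peg3 was 1.95-fold higher in E16 mesenchyme-like cells (1.60 to 2.37), while its epithelial value of 1.15-fold had an interval that includes 1 (0.799 to 1.66). Dlk1 was 2.17-fold higher in P4 epithelial-like cells (1.55 to 3.07), but it was a leading gene of mesenchyme-like clusters 1, 3, 7 and 9 against cells of other classes. The mesenchyme markers summed in epithelial-like cells also stood at 317 CPM in E16 and 1127 CPM in P4, so that the source of the Dlk1 transcripts stays open. Grb10 and Peg3 in mesenchyme-like cells and Peg3 and Igf2bp3 in epithelial-like cells were chosen after their values were seen, and differences between the tissues were not tested.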
